A study of Mus musculus with 12 samples.

How the data were processed

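RNA sequencing was done on testes of F1 mice that had received virus for overexpression or inhibition of lncRNA8276, a long non-coding RNA known here by that label. The labels place 12 libraries in 4 groups of 3, named here overexpression, knockdown, control_5NC and control_3NC. The groups called 5NC and 3NC in the labels are taken as the controls, and 5NC is set against overexpression and 3NC against knockdown because the design text lists them in that order. The labels name total RNA as the starting material and do not say whether the libraries of a group come from separate animals, so p-values measure the spread between these samples, which may be technical. Library replicate numbers come from the titles.

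The deposited table holds estimated counts per gene, per the file headers, and 88.2% of its values are whole numbers; the others carry fractions, as arise where reads are shared between similar genes. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program, the annotation, the strand setting and any filters are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The same table has 18 per-sample columns of 9 other samples, which were not used here. Genes are identified by symbol and Entrez number as deposited; 20630 of 20788 identifiers matched a RefSeq gene table, and positions for 20087 genes come from GENCODE M21 on GRCm38, which is the assembly behind mm10. Genes whose estimated counts carry fractions are described below as having shared counts and are uncertain. The level of lncRNA8276 was not analysed here.

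Estimated counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filterByExpr with the groups (minimum count 10), which left 16395 of 20788 genes; the 4393 genes left out, 301 of them at 0 in all libraries, held 0.0707% of the counts. Libraries were scaled by TMM, and 1 quasi-likelihood model of group means was fitted over all 12 libraries with robust dispersion, so that the groups of 3 share 1 estimate of the spread. The common dispersion was 0.0388, a biological coefficient of variation of 19.7%. Contrasts were tested with the quasi-likelihood F-test and p-values were adjusted by the Benjamini-Hochberg method within a contrast, with 0.05 as the threshold. Log2 fold changes are given ± the standard error of the fit, and levels as normalised CPM ± SD over libraries. For genes with a few counts in a group, the ratio of summed counts is given with its 95% counting interval, which covers counting error only; reads without molecular identifiers are not independent molecules.

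The comparisons were overexpression against control_5NC, knockdown against control_3NC, control_5NC against control_3NC, and the difference between the first 2 effects. Added after the data were seen were overexpression against knockdown and both modified groups together against both control groups. No library pair agreed within counting noise (chi-square per degree of freedom 3.08 to 39.7 within groups), so no pair was treated as copies of 1 library. On counts simulated from these libraries with 200 genes changed, the same test for overexpression against control_5NC recovered 28.4% of genes changed 1.5-fold, 61.2% at 2-fold and 92.4% at 4-fold, with 6.2% of calls false (16270 genes tested). For knockdown against control_3NC these shares were 13.4%, 70.1% and 89.4%, with 7.81% of calls false (16263 genes tested). Each comparison had 1 simulated draw, with independent libraries and no outlying library or batch. The shares of false calls need not hold for the real libraries.

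For each list of genes the test was camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the lists with at least 3 tested members, with camera at an estimated correlation and fry beside it. The 24 lists, fixed before the data were examined, were spermatogonia, meiotic prophase, pachytene and diplotene, round spermatid, elongating spermatid and sperm tail, Sertoli cell, Leydig cell and steroidogenesis, peritubular myoid cell, macrophage and leukocyte, endothelial cell, epididymis and rete testis, blood and erythroid, adipose tissue, cell-cell adhesion and junction, cell-matrix adhesion and extracellular matrix, MAPK signalling and immediate early, type I interferon response, stress and apoptosis, piRNA and retrotransposon silencing, DNA methylation and histone modification, oxidative phosphorylation, cytosolic ribosome, mitochondrially encoded, and replication-dependent histone. The mitochondrially encoded list had no tested member, which left 23 lists. Lists of liver and adrenal transcripts and of globins were added after the data were seen.

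Also fixed before the data were examined were the groups, the tests, most alternatives and the rule for named genes. That rule takes, per main comparison, the 10 largest rises and 10 largest falls among genes that passed, had a mean of at least 1 CPM and no overlap between groups of 3, without predicted genes and pseudogenes. Where fewer qualified, the genes with the smallest p filled up to 5 per direction. For the 2 control groups it takes 5 per direction, and for each list up to 4 members with the smallest p. A gene named outside this rule is marked as chosen after its values were seen.

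Alternatives were other scalings (DESeq2 median-ratio factors, upper quartile, total counts only), no filter or a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0 and limma-voom as tools, the replicate number as a block, a fit without robust estimation, a minimum fold of 1.2, a fit of the compared groups only, each library left out in turn, and the other control group or both. Chosen after the data were seen were a fit with a term for the 3 libraries with the lowest totals and a fit without 2 control_5NC libraries rich in epididymal transcripts. Correlations between contrasts that share controls were set against 20 simulations of unchanged groups. Closeness of genes on chromosomes was tested against 10000 random sets matched on expression, with a window of 2 Mb.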

Results

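RNA from F1 mouse testes was sequenced in 12 libraries, 3 each from testes given virus for overexpression of lncRNA8276, testes given virus for its knockdown, and 2 control groups, control_5NC and control_3NC. Libraries held 13485479 to 15771655 counts and detected 18616 to 18889 genes, and the 10 most abundant genes took 2.99% to 3.57% of a library. The first principal component carried 31.7% of the variance and the second 16.4%. The level of lncRNA8276 itself was not analysed here, so the group labels were not checked against their target.

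Several libraries stood apart from their groups. Control_3NC 2 had a median correlation of 0.948 with the other libraries, against 0.974 to 0.984 for the rest, and lay at 85.6 on the first component, where no other library passed 15.6. Its mean over the type I interferon list was 3.02 (log2) above the mean of all libraries and that over the macrophage and leukocyte list 2.28 above. Ptprc, the leukocyte surface antigen CD45, was at 95.5 CPM there and at 3.89 CPM or less elsewhere, and the antiviral gene Rsad2 at 37.1 CPM against at most 0.85. Crisp1, a sperm-coating protein of the epididymis, reached 240.0 CPM in control_5NC 2, 98.9 CPM in control_5NC 3 and 165.5 CPM in knockdown 1. Control_5NC 2, control_5NC 3 and overexpression 2 had 13485479 to 13847277 counts, and the other 9 libraries had 15252025 or more.

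Overexpression was set against control_5NC to find genes that differ when lncRNA8276 is raised. Alb, the serum albumin gene that liver cells express, rose from 0.0924 ± 0.0447 to 4.15 ± 1.71 CPM (SD, n = 3 per group), a ratio of summed counts of 45.8 (95% counting interval 17.6 to 170). Dchs1, which encodes a large cadherin of planar cell polarity, rose from 5.34 ± 0.102 to 25.7 ± 4.94 CPM, and Cyp21a1, the steroid 21-hydroxylase, from 5.16 ± 0.525 to 13.7 ± 2.30 CPM. Spo11, which cuts DNA to start meiotic recombination, fell from 62.0 ± 4.61 to 33.0 ± 2.62 CPM, and Cdk1, the kinase that drives entry into division, fell by 0.44 ± 0.080 (log2, SE). In all, 78 of 16395 tested genes passed edgeR's quasi-likelihood test, 42 higher and 36 lower in overexpression, with 2506 at an unadjusted p below 0.05. The count was 742 by DESeq2 (444 higher, 298 lower), 60 by limma-voom, 269 with the replicate number as a block (167 and 102) and 163 with total counts only (80 and 83). For 71 of these 78 genes control_5NC lay farther than overexpression from the mean of control_3NC and knockdown, and against control_3NC in place of control_5NC 1 gene passed, Alb (1097 at an unadjusted p below 0.05).

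Among the rises with the largest changes, the log2 fold change was 5.39 ± 0.52 for Alb (adjusted p = 0.00085), 2.27 ± 0.21 for Dchs1 (adjusted p = 0.00056), 1.92 ± 0.23 for Gtf2ird2, a member of the TFII-I transcription factor family (adjusted p = 0.0067), and 1.41 ± 0.18 for Cyp21a1 (adjusted p = 0.0089). Cst9, a cystatin of Sertoli cells, rose by 2.22 ± 0.38 (adjusted p = 0.045), from 10.1 ± 1.89 to 46.8 ± 2.01 CPM. Ryr1, the calcium release channel of skeletal muscle, rose by 1.56 ± 0.28 and the ubiquitin ligase gene Trim6 by 1.33 ± 0.24 (adjusted p = 0.035 each). A further 3 genes had 1 to 3 counts over the control_5NC group. Their ratios of summed counts were 212 (interval 37.7 to 8430) for the beta-globin gene Hbb-bs, whose counts are shared, 141 (47.8 to 684) for the pepsinogen gene Pga5, and 119 (21 to 4750) for the peptide hormone gene Cck, with adjusted p of 0.046, 0.035 and 0.045.

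The falls were smaller. Spo11 fell by 0.91 ± 0.10 on the log2 scale (adjusted p = 0.0033), Capns2, a calpain small subunit, by 1.54 ± 0.20 (adjusted p = 0.011), and Tgm6, a transglutaminase, by 1.59 ± 0.30 (adjusted p = 0.046). Tagap, with shared counts, and Sh2d7 each fell by 1.09, with errors of 0.18 and 0.17 (adjusted p = 0.028 and 0.019). Bcas1 fell by 0.88 ± 0.12 (adjusted p = 0.011), Marc2, a mitochondrial reductase, by 0.75 ± 0.11 (adjusted p = 0.017), and Tuft1 by 0.65 ± 0.094 (adjusted p = 0.017). Arhgef39 fell by 0.74 ± 0.14 (adjusted p = 0.048), and Aurkb, the Aurora kinase of chromosome segregation, by 0.73 ± 0.12 (adjusted p = 0.03). On GRCm38, Dchs1 lies on chromosome 7 at 105752990 to 105787654, Trim6 on the same chromosome at 104218793 to 104235152 and Hbb-bs at 103826534 to 103828096. Alb lies on chromosome 5 at 90460897 to 90476602, Cyp21a1 on chromosome 17 at 34801348 to 34804561 and Spo11 on chromosome 2 at 172977700 to 172993576, all annotated as protein-coding.

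**Figure D1:**
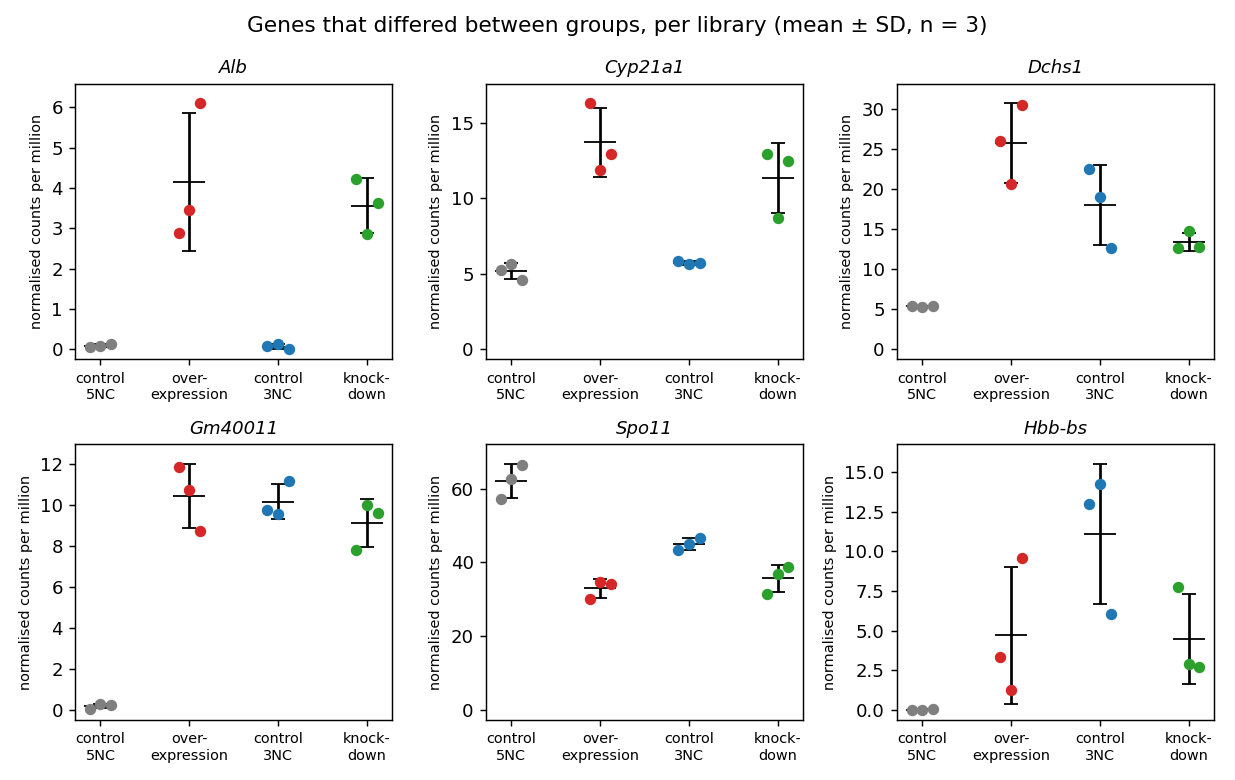
Normalised CPM of 6 genes in each of the 12 libraries, by group (points: libraries, horizontal lines and bars: mean ± SD, n = 3). Alb and Cyp21a1 were higher in overexpression and knockdown than in both control groups, while Dchs1, Gm40011 and Hbb-bs were lowest in control_5NC and Spo11 was highest there.

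Genes of late sperm formation were higher in overexpression than in control_5NC as groups. Of 28 round spermatid genes, which build the acrosome and pack sperm chromatin, 9 were higher and 1 lower adjusted over the list alone and 0 over all genes. The median log2 fold change was 0.28 (camera, adjusted p = 0.00243; adjusted p = 0.989 with an estimated correlation). Acrv1, an acrosomal protein gene, was at 0.52 ± 0.13, Spaca3 at 0.55 ± 0.14, Sun5 at 0.53 ± 0.14 and Izumo1, which sperm need to fuse with the egg, at 0.47 ± 0.13, with adjusted p over all genes from 0.099 to 0.12. Of 29 elongating spermatid and sperm tail genes, 8 were higher and 1 lower adjusted over the list alone and 0 over all genes, with a median of 0.22 (adjusted p = 0.0124; adjusted p = 0.989 with an estimated correlation). Odf1, an outer dense fibre protein, was at 0.67 ± 0.19, Spata18 at 0.44 ± 0.10, Catsper1, a sperm calcium channel subunit, at 0.48 ± 0.14 and Oaz3, with shared counts, at 0.52 ± 0.13 (adjusted p 0.082 to 0.13). Of 14 adipose genes, 2 were higher adjusted over the list alone, Adipoq (0.61 ± 0.15, adjusted p over all genes = 0.094) and Acsl1 (0.34 ± 0.096, 0.125), and 0 over all genes, with a median of 0.40 (adjusted p = 0.0282; adjusted p = 0.989 with an estimated correlation). Without overexpression 3 the adjusted p was 0.0605 for elongating spermatid genes and 0.549 for adipose genes, and without control_5NC 2 it was 0.137 for adipose genes. Round spermatid genes passed without each of the 6 libraries in turn (adjusted p 0.000103 to 0.0411). With a term for the 3 libraries with the lowest totals, the adjusted p was 0.0288 for both spermatid lists and 0.161 for adipose genes.

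Earlier germ cells showed single genes. Of 36 meiotic prophase genes Spo11 was lower over all genes, and Syce2, of the synaptonemal complex, was higher adjusted over the list alone (0.64 ± 0.13, adjusted p over all genes = 0.06). The list's median was -0.00621 and its mean 0.0102 (adjusted p = 0.929). Of 24 pachytene and diplotene genes Cdk1 was lower over all genes (adjusted p = 0.035) and Ccna1, cyclin A1, lower adjusted over the list alone (-0.37 ± 0.077). The median was -0.135 (adjusted p = 0.178). Spermatogonia genes had a median of -0.03 with 0 members passing in either way (adjusted p = 0.889), and the nearest was Rhox13 (0.61 ± 0.21, adjusted p = 0.19).

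Other cell types and processes gave no passing list in this comparison. Median log2 fold changes were 0.0127 for Sertoli cell genes, where Cst9 passed, 0.141 for Leydig cell genes, -0.0143 for peritubular myoid cell genes, 0.0732 for endothelial genes, -0.101 for macrophage and leukocyte genes and -0.364 for type I interferon genes. They were -0.362 for epididymis genes, which follow Crisp1 in control_5NC 2 and control_5NC 3, and -0.0903 for blood and erythroid genes, where Hbb-bs passed and Hbb-b1, with shared counts, was at -0.84 ± 0.26. Cell-cell adhesion genes had a median of -0.0309, cell-matrix genes -0.0639, MAPK and immediate early genes -0.0875, stress and apoptosis genes 0.0225, piRNA genes -0.00912, DNA methylation and histone genes -0.00223, oxidative phosphorylation genes 0.00807, cytosolic ribosome genes -0.0305 and replication-dependent histone genes 0.302, the last over 6 tested genes. Adjusted p for these lists lay between 0.636 and 0.982. Adjusted over the list alone, Egr3, an immediate early gene, the histone deacetylase gene Hdac11, Hbb-bt and the histone genes Hist1h4a and Hist1h3a, with shared counts, were also higher, and Kdm4d, a histone demethylase gene, Aqp9, a water channel gene of the epididymis list, and Hbb-b1 were lower. The mean had the opposite sign to the median in the blood, MAPK, stress, DNA methylation, oxidative phosphorylation and ribosome lists, and camera's direction followed the mean for blood, stress and oxidative phosphorylation genes and the median for the other 3.

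The number of genes depended on single libraries: it was 14, 13 and 5 without control_5NC 1, 2 and 3, and 5, 217 and 8 without overexpression 1, 2 and 3. Alb, Dchs1 and Spo11 passed in all 6 of these fits. Cst9 and Tgm6 passed in 0 of 6, with adjusted p of 0.05 to 0.22 and 0.053 to 0.24. Hbb-bs, Pga5, Cck, Ryr1, Trim6, Tagap, Sh2d7, Marc2, Arhgef39, Aurkb, Tuft1 and Cdk1 passed in 1 of 6, the fit without overexpression 2. Gtf2ird2 and Cyp21a1 passed in 4 and lost the call without control_5NC 3 or overexpression 1. Bcas1 passed in 3 (without control_5NC 1, control_5NC 2 or overexpression 2) and Capns2 in 2 (without control_5NC 2 or overexpression 2). With a term for the 3 libraries with the lowest totals, Cst9 (adjusted p = 0.093), Cck (0.089), Pga5 (0.085), Arhgef39 (0.076), Hbb-bs (0.072), Ryr1 (0.061) and Trim6 (0.057) did not pass. The count with this term was 56, of which 46 were shared.

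**Figure D2:**
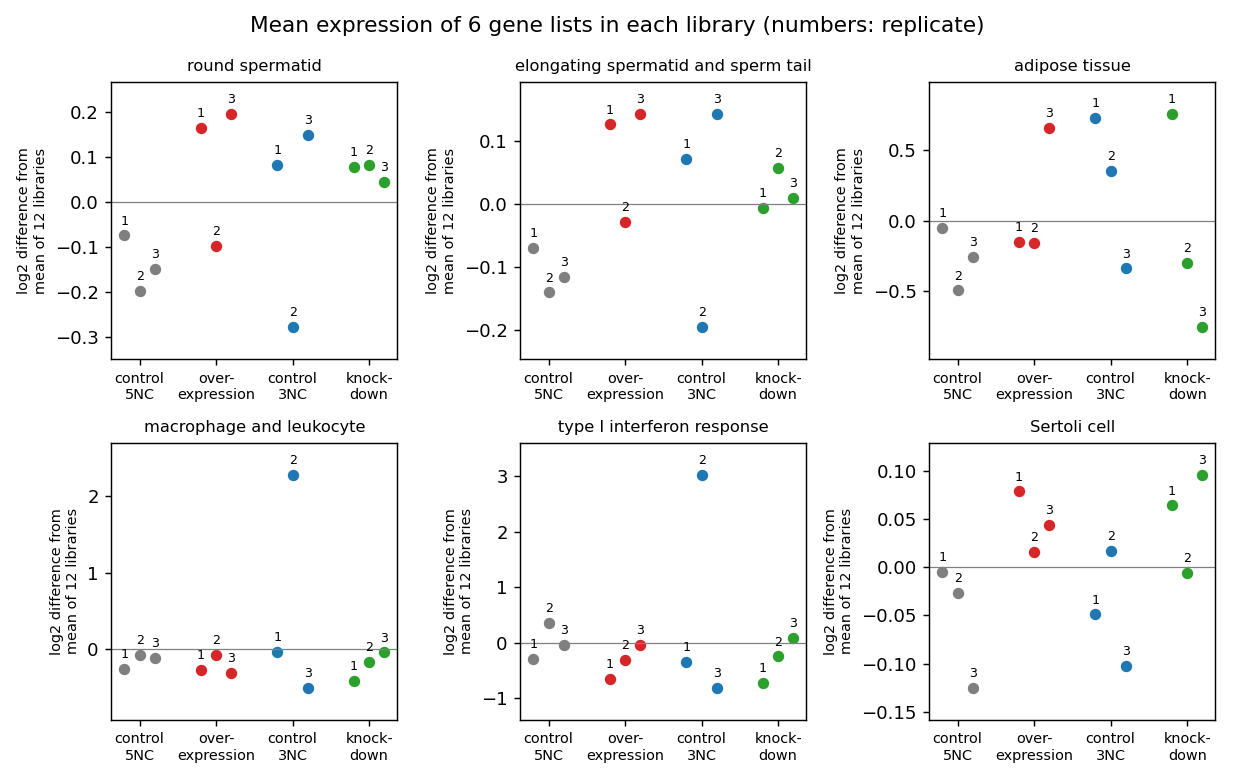
Mean log2 expression of 6 gene lists in each library, as the difference from the mean of 12 libraries (points: libraries, numbers: replicate). Control_3NC 2 lies 2.28 above the mean for macrophage and leukocyte genes and 3.02 above it for type I interferon genes, and round spermatid genes lie below 0 in the 3 control_5NC libraries, in overexpression 2 and in control_3NC 2.

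Knockdown was set against control_3NC to find genes that differ when lncRNA8276 is lowered. Alb rose from 0.0639 ± 0.0626 to 3.57 ± 0.683 CPM (SD, n = 3 per group), a ratio of summed counts of 54.5 (interval 18.3 to 267), and Neo1, a receptor for netrins, rose from 57.4 ± 1.89 to 91.4 ± 3.73 CPM. Gm15127, an X-linked gene with shared counts chosen after its values were seen, fell from 6.05 ± 0.441 to 1.94 ± 0.572 CPM. These 3 genes were all that passed edgeR's test, with 1424 genes at an unadjusted p below 0.05, 23 genes by DESeq2 and 3 by limma-voom. The log2 fold changes were 5.6 ± 0.54 for Alb (adjusted p = 0.0035), 0.67 ± 0.085 for Neo1 (adjusted p = 0.021) and -1.64 ± 0.20 for Gm15127 (adjusted p = 0.0168). On GRCm38, Neo1 lies on chromosome 9 at 58874687 to 59036441 and Gm15127 on chromosome X at 148663598 to 148703849.

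Genes that came next did not pass. Cyp21a1 was at 11.4 ± 2.33 CPM in knockdown and 5.72 ± 0.106 in control_3NC (log2 0.99 ± 0.18, adjusted p = 0.3), and Hsd3b1, a steroid dehydrogenase of Leydig cells, at 138.9 ± 10.4 and 101.3 ± 5.52 (0.46 ± 0.083, adjusted p = 0.3). The amino acid transporter gene Slc6a15 had a ratio of summed counts of 16.1 (interval 5.19 to 80.7; adjusted p = 0.3). Lower values with adjusted p of 0.3 were those of Sirpb1b (-1.58 ± 0.28, shared counts) and Pop4, a subunit of ribonuclease P (-0.70 ± 0.13). Cd7, a T cell antigen, was at -2.07 ± 0.46, Ankrd12 at -0.43 ± 0.095 and Vmn1r181, a vomeronasal receptor gene, at -1.24 ± 0.28 (adjusted p = 0.56 each). Spo11 was at -0.33 ± 0.10 (adjusted p = 0.56).

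Macrophage and leukocyte genes and type I interferon genes were lower in knockdown than in control_3NC as groups, along with the high values of these genes in control_3NC 2. The 21 leukocyte genes had a median of -1.24, 20 of them below 0 and 0 passing over all genes or adjusted over the list alone (camera, adjusted p = 0.002; adjusted p = 0.959 with an estimated correlation). Ptprc was at -3.70 ± 1.2, the integrin gene Itgam at -3.07 ± 1.1 and the macrophage receptor gene Adgre1 at -1.24 ± 0.47 (adjusted p = 0.56 each). The 25 interferon genes had a median of -2.12 with 0 passing in either way (adjusted p = 0.0112; adjusted p = 0.959 with an estimated correlation), and Rsad2 was at -4.77 ± 1.7, Ifit2 at -4.30 ± 1.5, Ifi44 at -4.17 ± 1.5 and Oasl1 at -2.57 ± 0.79. Without control_3NC 2 the leukocyte median was 0.0949 (adjusted p = 0.511) and the interferon median 0.412 (higher in knockdown, adjusted p = 0.0148; adjusted p = 0.842 with an estimated correlation). Without knockdown 1 the interferon list had an adjusted p of 0.105. Sertoli cell genes had a median of 0.15 over 29 genes (adjusted p = 0.0358; adjusted p = 0.75 with an estimated correlation), with 1 higher adjusted over the list alone, the transcription factor gene Gata1 (0.49 ± 0.12), and 0 over all genes. Amh, the anti-Mullerian hormone gene, was at 0.89 ± 0.33. This list had an adjusted p of 0.152 without control_3NC 1, 0.0828 without control_3NC 3 and 0.0994 without knockdown 3.

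Germ cell lists had small values in knockdown, with medians of 0.0904 for spermatogonia, -0.0223 for meiotic prophase, -0.0156 for pachytene and diplotene, 0.0518 for round spermatid and -0.00511 for elongating spermatid genes. Medians were 0.206 for peritubular myoid, 0.0286 for Leydig, -0.056 for endothelial, 0.428 for epididymis, 0.0851 for blood and -0.153 for adipose genes, and the epididymis value goes with Crisp1 in knockdown 1. Stress and apoptosis genes had a median of -0.105, cytosolic ribosome genes -0.065, cell-matrix genes -0.0453, MAPK genes -0.0253, oxidative phosphorylation genes -0.00565, cell-cell adhesion genes 0.0173, DNA methylation and histone genes 0.0212, piRNA genes 0.0268 and replication-dependent histone genes 0.199. Median and mean had opposite signs in the pachytene, elongating spermatid, Leydig, blood and DNA methylation lists, and camera's direction was up for the cell-matrix, MAPK and oxidative phosphorylation lists, whose median and mean lay below 0. None of these 20 lists passed by camera (adjusted p 0.0912 to 0.892; 0 by fry), and of their members Hsd3b1 was higher adjusted over the list alone. Counts of genes were 1, 2 and 9 without control_3NC 1, 2 and 3, and 1, 1 and 2 without knockdown 1, 2 and 3. Alb passed in all 6 of these fits, Neo1 in 1, and fitting only the 6 libraries compared gave 0 genes by edgeR (in the fit of all groups 3, with 1424 at an unadjusted p below 0.05, 23 by DESeq2 and 3 by limma-voom).

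Control_5NC was set against control_3NC to show how far the control groups differ. Beta-globin genes went both ways. Hbb-b1 was at 27.6 ± 6.87 CPM in control_5NC and 8.54 ± 1.23 in control_3NC, while Hbb-bs was at 0.024 ± 0.0415 and 11.1 ± 4.42 (SD, n = 3 per group, shared counts for both). Hbb-b1 had no position on GRCm38. Summed globin CPM was 62.5, 79.3 and 61.6 in control_5NC 1, 2 and 3, and 74.3, 55 and 29.7 in control_3NC 1, 2 and 3. The globins together were thus not lower in control_5NC, which argues against a general loss of globin transcripts there. For single globin genes, these values cannot tell a change in expression from a difference in parental haplotype. Capns2 was higher in control_5NC, at 4.13 ± 0.239 against 1.14 ± 0.128 CPM, and Gtf2ird2 lower, at 4.15 ± 0.357 against 18.3 ± 4.46 CPM. In all, 40 genes passed edgeR's test, 15 higher and 25 lower in control_5NC (2111 at an unadjusted p below 0.05; 305 genes by DESeq2 and 13 by limma-voom). Higher were Capns2 (1.85 ± 0.21, adjusted p = 0.0041), Zmynd8, a chromatin reader with shared counts (1.2 ± 0.15, adjusted p = 0.0085), Hbb-b1 (1.69 ± 0.27, adjusted p = 0.037) and Bcas1 (0.75 ± 0.12, adjusted p = 0.037). Slc6a15 was higher with a ratio of summed counts of 30.2 (interval 10 to 149; adjusted p = 0.012). Lower were Gtf2ird2 (-2.14 ± 0.23, adjusted p = 0.0041) and Trim5, a restriction factor gene with shared counts (-4.14 ± 0.70, adjusted p = 0.04). Ratios of summed counts, control_3NC over control_5NC, were 491 (87.8 to 19400) for Hbb-bs, 157 (53.5 to 766) for Pga5 and 122 (21.5 to 4850) for Hbb-bt, a further beta-globin gene (adjusted p 0.037, 0.043 and 0.049).

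Among gene groups, oxidative phosphorylation genes were higher in control_5NC (35 genes, 31 above 0, median 0.094, adjusted p = 0.0169; adjusted p = 0.165 with an estimated correlation), with 0 passing in either way and Cox4i1 at 0.23 ± 0.080 (adjusted p = 0.29). Pachytene and diplotene genes had a median of 0.0724 over 24 genes (adjusted p = 0.0252; adjusted p = 0.933 with an estimated correlation). Adjusted over the list alone 4 of them were higher, Cdk1 (0.39 ± 0.080), Ccna1 (0.35 ± 0.077), Aurka (0.28 ± 0.079) and Pou5f2 (0.61 ± 0.13), and 0 over all genes. Macrophage and leukocyte genes were lower (21 genes, median -1.31, adjusted p = 0.0252; adjusted p = 0.933 with an estimated correlation), with 0 passing in either way. Control_3NC 2, with its high leukocyte values, enters this comparison too. Without control_3NC 2 these lists had adjusted p of 0.0616, 0.653 and 0.301, the last with a median of 0.154; without control_5NC 1 it was 0.0793 for leukocyte genes, and without control_5NC 3 it was 0.104 for pachytene genes. With a term for the 3 libraries with the lowest totals it was 0.198 for pachytene and 0.0641 for leukocyte genes. The other 20 lists had adjusted p of 0.0906 to 0.907, with medians of -0.162 for round spermatid, -0.172 for elongating spermatid, -0.585 for adipose and -1.80 for type I interferon genes. Adjusted over their lists alone and not over all genes, Srd5a1, a steroid reductase gene, Spo11, Aqp9, Hbb-b2 and the laminin genes Lama2 and Lamc3 were higher in control_5NC, and Cst9, Acsl1, the integrin gene Itga1 and S100a9 were lower. Median and mean differed in sign in the Sertoli, blood and cell-cell adhesion lists, and camera's direction was up for the Leydig, cell-matrix and DNA methylation lists, whose median and mean lay below 0. The count of 40 genes was 22, 126 and 59 without control_3NC 1, 2 and 3, and 10, 8 and 7 without control_5NC 1, 2 and 3. It was 6 with the term for the 3 libraries, and 2 without control_5NC 2 and control_5NC 3, the control_5NC libraries with epididymal reads.

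The comparisons of overexpression and of control_3NC with control_5NC shared 20 genes, and these 2 sets share the control_5NC libraries. Simulated unchanged groups gave 0.05 shared genes on average and 1 at most, and independent lists would share 0.064 genes higher and 0.033 lower. Unchanged groups have few calls to share, and independent lists share no libraries. Neither therefore shows how many real calls the shared libraries would give, here or for knockdown below. Across genes, which are not independent replicates, the fold changes correlated at -0.477 (simulated -0.503), with a covariance of -0.122 against -0.0632 simulated, a difference of -0.0587. Knockdown against control_5NC passed 202 genes, of which 56 were among the 78 of overexpression in the same direction (simulated mean 0.05, highest 1; independent lists 0.25 higher and 0.23 lower). That correlation was 0.756 (simulated 0.496) and the covariance 0.164 against 0.0623, a difference of 0.101. The 3 control libraries cannot be split into parts of at least 2. Part or all of these overlaps, and part of the excess in covariance, may thus come from the shared controls.

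**Figure D3:**
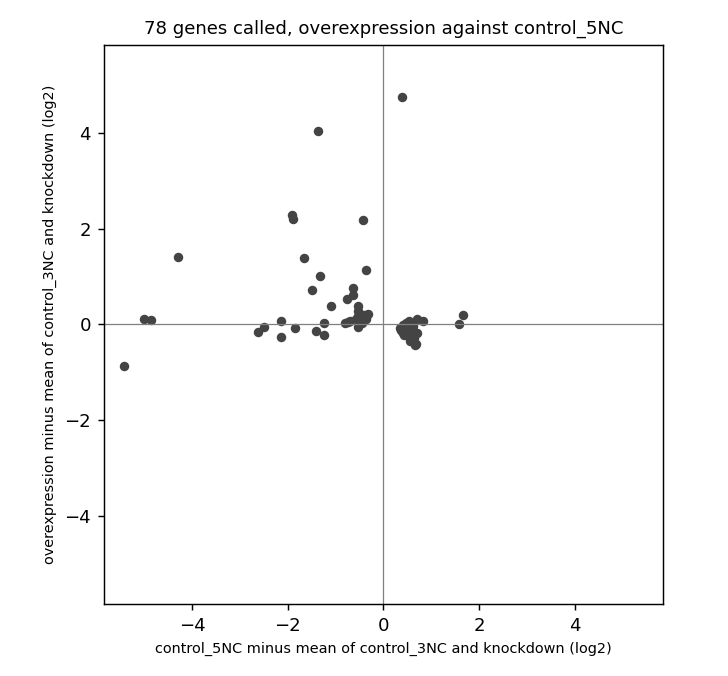
The 78 genes that passed between overexpression and control_5NC, with the log2 distance of control_5NC (horizontal) and of overexpression (vertical) from the mean of control_3NC and knockdown (points: genes). For 71 of the 78 the control_5NC distance is the larger.

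The effects of overexpression and knockdown, each against its own control, differed for 3 genes by edgeR's test of the difference (1104 at an unadjusted p below 0.05; 53 genes by DESeq2 and 3 by limma-voom). These were Dchs1, with a difference of 2.69 ± 0.28 on the log2 scale (adjusted p = 0.0026), and 2 predicted genes chosen after their values were seen, A530064D06Rik (6.15 ± 0.52, adjusted p = 4e-04) and Gm40011 (5.93 ± 0.37, adjusted p = 2.2e-05). In knockdown against control_3NC the log2 fold change of Dchs1 was -0.43, that of A530064D06Rik 0.12 and that of Gm40011 -0.16. In control_5NC against control_3NC it was -1.75 for Dchs1 (adjusted p = 0.0054), -6.1 for A530064D06Rik (adjusted p = 4.8e-05) and -5.73 for Gm40011 (adjusted p = 3e-06). Gm40011 was at 0.187 ± 0.113 CPM in control_5NC and at 10.4 ± 1.56 in overexpression, 10.2 ± 0.867 in control_3NC and 9.12 ± 1.17 in knockdown (SD, n = 3 per group). A530064D06Rik, with shared counts, was at 0.0654 ± 0.063 CPM in control_5NC and between 5.23 and 5.91 in the other groups. All 3 passed without each of the 12 libraries in turn, and the count was 5 without control_3NC 2, knockdown 3 or overexpression 2, 6 without knockdown 1 and 12 without control_3NC 3. Among gene lists the difference had a median of 0.252 for 29 elongating spermatid and sperm tail genes and 0.67 for 14 adipose genes (camera, adjusted p = 0.0321 each; adjusted p = 0.828 each with an estimated correlation), with 0 members passing in either way.

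Across 16395 genes the overexpression and knockdown fold changes, which share no library, correlated at 0.171 (Pearson) and 0.286 (Spearman), with 62.5% of genes of the same sign. Genes are not independent replicates. Without control_3NC 2 the Pearson value was -0.00676. Of the 78 genes of overexpression 55 had the same sign in knockdown, and 1, Alb, passed in both.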

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

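Of the tests below, the share of genes for which control_5NC lay farther, the closeness of genes on chromosomes, the shifts in control_5NC 1, and the tests of control_3NC 2 and of globins were chosen after the results were seen; the counts of other splits and the tests of the difference between effects were planned.

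The overexpression and knockdown effects differed for A530064D06Rik by 6.15 (log2), for Dchs1 by 2.69 and for Gm40011 by 5.93, by edgeR's test of the difference between the effects. These 3 genes also differed between the control groups, with log2 values of -6.1, -1.75 and -5.73 in control_5NC against control_3NC, so most of each difference lies in the controls. Between overexpression and knockdown edgeR called 0 genes (343 at an unadjusted p below 0.05; DESeq2 12, limma-voom 0). A530064D06Rik and Gm40011 were chosen after their values were seen. Of 100 drawn regroupings of the 12 libraries, 1, the real one, gave as many as 3 genes, and the highest of the others gave 2. The draws move single libraries, so they cannot exclude a chance difference of a whole group such as control_5NC. By camera the lists of elongating spermatid and sperm tail genes (median difference 0.252) and adipose genes (0.67) also differed, and neither passed with an estimated correlation (adjusted p = 0.828 each). In control_5NC against control_3NC these lists had medians of -0.172 and -0.585, but neither passed (camera, adjusted p = 0.0954 each, and 0.933 each with an estimated correlation). Part of these differences may thus lie in the controls.

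Of the 78 genes that passed between overexpression and control_5NC, the first pattern weighed, 91% (71 genes; 84.6% to 93.6% over the 9 pairs of single libraries) had control_5NC farther than overexpression from the mean of control_3NC and knockdown. This argues against overexpression alone having moved most of these 71 away from a level shared by the other 3 groups, but not for the 7 others, Alb, Cck, Cyp21a1, Ryr1, Gm21466, Gm2854 and Gm5923. The mean includes knockdown, so it cannot argue against a change in both modified groups. Some of the 71 also passed between both modified and both control groups with no overlap of their libraries. These were Serpina3k, Spo11, Marc2, Tuft1, Tcp10a, Tagap, Rfx8, Tmem202, Gm46310 and Trappc12. Epididymal tissue in control_5NC 2 and 3 is argued against for the 14 genes that passed without control_5NC 1 (13 of them among the 78), since in that library, with 9.93 CPM of Crisp1, they shifted 0.911 times as far as in the other two (median; interquartile range 0.771 to 1.06); for the rest it stays open, because that library helped to choose them and, of 78 genes ranked first without it, 26.9% shifted less than 0.5 times as far (21 genes). A candidate explanation that stays open is that the control_5NC animals carry other parental haplotypes than the rest: 24 of 72 genes with a position lay within 2 Mb of another such gene, against 12.4 on average in 10000 random sets matched on expression, of which a share of 0.0081 had at least as many, and Hbb-bs was at 0.024 CPM and Hbb-bt at 0.0235 CPM in control_5NC, where Hbb-b1 was at 27.6 CPM. For control_5NC against control_3NC it was 11 of 38 against 3.65 (a share of 0.0073). For knockdown against control_5NC it was 89 of 194 against 74.3 (a share of 0.049, inside the middle 95% of random sets). Closeness does not separate haplotypes from shared regulation of neighbouring genes. Overlapping neighbours, such as Antxrl, which lies within A630023A22Rik, may also share reads. The random sets, matched on expression alone, do not copy this. An effect of the control virus on these animals was not tested.

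The leukocyte and interferon lists, lower in knockdown than in control_3NC, form the second pattern. That control_3NC 2 alone carried it is in line with the fit without that library, where the leukocyte list had an adjusted p of 0.511 and the interferon list had a median of 0.412, higher in knockdown (adjusted p = 0.0148; adjusted p = 0.842 with an estimated correlation). Peripheral blood in that library is argued against: summed globin CPM stood at 0.9 times the median of the other 11 libraries, Hba-a1 at 0.748 times and Alas2 at 1.11 times, while 21 leukocyte genes had a median ratio of 4.39 (interquartile range 3.1 to 11). The blood and erythroid list went the other way, with its highest mean in that library (1.17 above that of all libraries). There S100a9, a gene of neutrophils, stood at 43.7, Hbb-bs at 4.87, Hbb-bt at 4.76 and Ltf at 3.62 times the median of the other 11. Hbb-b1 stood at 0.558 and Hbb-b2 at 0.494 times. Against the highest of the other 11, Hbb-bs was at 14.2 and 13 CPM, and Ltf at 2.38 and 4.92 CPM. Hbb-bs and Hbb-bt were near 0 in control_5NC, which lowers their medians. An infection or inflammation of that testis stays open and was not tested.

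Other splits of the 6 libraries of a comparison are 10 in number, too few for a share under 0.05. For overexpression against control_5NC 2 of 10 splits gave at least the real 78 genes, and the highest other gave 773; it sets control_5NC 2, control_5NC 3 and overexpression 2, the libraries with the lowest totals, against the rest and points to a structure of the samples, and with a term for these libraries 56 genes passed. For its gene lists 2 of 10 splits gave at least 3 (highest other 4). For knockdown against control_3NC 1 of 10 gave at least 3 genes (highest other 2) and 8 of 10 at least 3 lists (highest other 16), which also points to a structure of the samples: the 6 splits that part control_3NC 2 from control_3NC 3 gave 11 to 16 lists. For control_5NC against control_3NC 1 of 10 gave at least 40 genes (highest other 0) and 8 of 10 at least 3 lists (highest other 15, again a split that parts control_3NC 2 from control_3NC 3). For the correlation between the overexpression and knockdown fold changes 14 of 100 regroupings gave a value as large as 0.171 (highest other 0.279), so chance cannot be excluded.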

How the results depend on the processing

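The terms for the 3 libraries with the lowest totals, the fits without 2 control_5NC libraries, and all results of overexpression against knockdown and of both modified against both control groups were chosen after the data were seen; the other alternatives were planned. Over all alternatives 72 values of counts or correlations moved and 1 reversed. Of values for named genes 3485 kept their status, which includes genes that passed in neither fit, 77 gained a call and 84 lost one. A further 23 changed sign without passing in either fit and 0 reversed while passing. Most named genes are list members that did not pass in the main fit, so the 3485 do not measure how stable the calls were. Unless stated, the cause of a move was not tested. For overexpression against control_5NC (78 genes), DESeq2 gave 742 (67 shared), total counts only 163 (80 higher, 83 lower), a minimum fold of 1.2 gave 9, both control groups together 9, control_3NC as the control 1, and the fit without the 2 control_5NC libraries with epididymal reads, which has fewer samples, 2. Leaving out 1 library gave 5 (control_5NC 3 or overexpression 1) to 217 (overexpression 2). For knockdown against control_3NC (3 genes), DESeq2 gave 23, both control groups together 14 and control_5NC as the control 202. Only the groups compared gave 0 by edgeR, against 1424 genes at an unadjusted p below 0.05 in the fit of all groups and 3 by limma-voom. Leaving out 1 library gave 1 to 9 (control_3NC 3). For control_5NC against control_3NC (40 genes), DESeq2 gave 305, limma-voom 13, a minimum fold of 1.2 gave 11, only the groups compared 9, total counts only 68 (34 higher, 34 lower, against 15 and 25), the term for the 3 libraries 6, and the fit without 2 control_5NC libraries 2. Leaving out 1 library gave 7 (control_5NC 3) to 126 (control_3NC 2). For the difference between the effects (3 genes), DESeq2 gave 53 and leaving out 1 library 3 to 12 (control_3NC 3). For both modified against both control groups (43 genes), DESeq2 gave 675, total counts only 68, a minimum fold of 1.2 gave 7, and leaving out 1 library 6 (control_5NC 3, knockdown 2 or overexpression 1) to 300 (overexpression 2). It was 266 without control_3NC 3, and 18, 15, 28, 13 and 12 without control_5NC 1, control_5NC 2, knockdown 1, knockdown 3 and overexpression 3. For overexpression against knockdown edgeR called 0 genes (343 at an unadjusted p below 0.05), limma-voom 0 and DESeq2 12, and leaving out 1 library gave 0 to 2 (overexpression 2; 1 without knockdown 3). The correlation of 0.171 was 0.0433 with no filter, and -0.00676 (control_3NC 2 left out, a reversal) to 0.23 (knockdown 1) without 1 library. Gene lists called, 3 each for overexpression, knockdown and the control groups, were 0 in each with an estimated correlation. For control_5NC against control_3NC they were 5 with total counts only and 1 with the term for the 3 libraries. Without 1 library they were 1 (overexpression 3) to 3 for overexpression, 2 to 7 for knockdown (7 without control_3NC 3, 6 without control_3NC 2, 5 without knockdown 1) and 2 to 7 (control_3NC 3) for the control groups.

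Whether the replicate numbers pair the samples stays open. Deviations from group means of same-numbered libraries correlated at 0.21, 0.31 and -0.12 between overexpression and control_5NC, 0.038, -0.039 and -0.093 between knockdown and control_3NC, and 0.3, 0.18 and 0.0032 between the control groups. Some libraries correlated best with their own number and others did not. With the replicate number as a block the counts were 269 for overexpression, 3 for knockdown, 54 for the control groups, 6 for the difference, 386 for both modified groups and 0 for overexpression against knockdown, with 3 gene lists in each of the first 3 comparisons. In single simulated draws at this depth the test recovered 28.4% of genes changed 1.5-fold for overexpression and 13.4% for knockdown, so smaller changes would mostly go undetected.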

Other observations

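The comparisons of both modified groups with both control groups and of overexpression with knockdown, the tests on scarce liver and adrenal cortex genes, and the closeness of genes on chromosomes, were chosen after the data were seen; the predictions for the liver and adrenal medians were written before their results.

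Across both modified groups together (n = 6) against both control groups (n = 6), 43 genes passed edgeR's test, 22 higher and 21 lower, named here after their values were seen. In 20 of the 43 the modified and control libraries overlapped, among them Gm40011, A530064D06Rik, Dchs1 and Gtf2ird2, which were low in control_5NC alone. The count was 675 by DESeq2, and without 1 library it ran from 6 (control_5NC 3, knockdown 2 or overexpression 1) to 300 (overexpression 2). It was 266 without control_3NC 3, and 18, 15, 28, 13 and 12 without control_5NC 1, control_5NC 2, knockdown 1, knockdown 3 and overexpression 3. Alb rose by 5.49 ± 0.38 (log2, SE; adjusted p = 3.3e-05), Cyp21a1 by 1.2 ± 0.13 (adjusted p = 0.002) and Serpina3k, a serine protease inhibitor of liver, by 2.83 ± 0.41 (adjusted p = 0.02), from 0.112 ± 0.0828 to 0.784 ± 0.165 CPM. Spo11 fell by 0.62 ± 0.072 (adjusted p = 0.0039), from 53.5 ± 9.87 to 34.3 ± 3.22 CPM, Marc2 fell by 0.57 ± 0.076 (adjusted p = 0.014) and Col17a1, a collagen of hemidesmosomes, fell by 0.83 ± 0.13 (adjusted p = 0.024). Tcp10a, a testis gene of chromosome 17, fell by 0.35 ± 0.050 (adjusted p = 0.02), from 337 ± 36.5 to 264 ± 8.62 CPM. Among multicopy genes of the X chromosome, Gm15114 fell by 4.35 ± 0.61 and Gm15127 by 1.17 ± 0.13, while Gm15128 rose by 1.54 ± 0.25 (adjusted p = 0.02, 0.0039 and 0.035). Of 100 drawn regroupings 1, the real one, gave as many genes, and the highest other gave 1. The draws move single libraries and break up the groups. They therefore cannot tell an effect shared by the modified groups from other differences between whole groups. Of 38 of these genes with a position 11 lay within 2 Mb of another, against 3.67 on average in random sets matched on expression (a share of 0.0075 had as many). The limits of closeness given above hold here too. Round spermatid genes had a median of 0.192 (camera, adjusted p = 0.00997; adjusted p = 0.988 with an estimated correlation), 9 higher and 2 lower adjusted over the list alone and 0 over all genes. This call rests on control_3NC 2, the lowest library for the list (-0.279 from the mean of all 12): without it the median was 0.134 (adjusted p = 0.131). The other control_3NC libraries, at 0.0823 and 0.149, lay among or above the knockdown libraries, at 0.0449 to 0.0824.

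Between overexpression and knockdown 0 genes passed edgeR's test (343 at an unadjusted p below 0.05; DESeq2 12, limma-voom 0); 10 of the 10 splits of these libraries gave as many (highest other 0), which for a count of 0 carries no information. As a group, oxidative phosphorylation genes were higher in overexpression (35 genes, 29 above 0, median 0.0872, camera, adjusted p = 0.00125; adjusted p = 0.0615 with an estimated correlation), and without each of the 6 libraries in turn the adjusted p was 0.000107 to 0.0476. Leydig cell genes were higher (27 genes, 21 above 0, median 0.19, adjusted p = 0.00472; adjusted p = 0.946 with an estimated correlation) and peritubular myoid genes lower (20 genes, median -0.196, adjusted p = 0.0256; adjusted p = 0.946 with an estimated correlation). Both calls rest on knockdown 1, whose mean for epididymis genes lay 1.47 (log2) above that of all 12 libraries: without it their medians were 0.0283 (adjusted p = 0.728) and 0.000487 (adjusted p = 0.974), and without overexpression 3 the myoid list had an adjusted p of 0.111. No member of these lists passed over all genes or adjusted over the list alone. For oxidative phosphorylation genes, control_5NC stood above control_3NC by a median of 0.094, no less than overexpression above knockdown. The overexpression and knockdown effects on this list, each against its own control, differed by a median of 0.00395 (camera, adjusted p = 0.623). The higher values of this list in overexpression thus cannot be credited to the modification.

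Alb and Cyp21a1, chosen because they separate the groups, were higher in each of the 6 modified libraries than in any of the 6 control libraries (3.86 ± 1.21 against 0.0781 ± 0.0511 CPM and 12.5 ± 2.43 against 5.44 ± 0.458 CPM, SD), the third pattern weighed. Medians decide neither source, 0.136 over 4 tested adrenal genes and 0.419 over 17 tested of 27 liver genes: the bounds set for them before were wrong, because 4 of the 4 and 15 of the 17 exceed 0.5 CPM in the control libraries, a baseline that hides a small share. Adrenal cortex RNA is argued against for Cyp21a1 by Cyp11b1, Cyp11b2 and Mc2r, which together were at 0.254 CPM in the modified (upper 95% limit 0.382) and 0.2 CPM in the control libraries, against an excess of Cyp21a1 of 7.1 CPM; of the same list Akr1b7 was at 93.2 CPM in knockdown 1 and 2.92 CPM in knockdown 2, but at 0.88 CPM or less in overexpression. The 12 liver genes scarce in these testes, Alb left out, summed to 4.61 ± 1.5 CPM in the modified and 1.33 ± 0.384 CPM in the control libraries (exact two-sided permutation p = 0.00216, the smallest that 924 splits can give; ratio 3.47, against a median of 0.942 over 10000 random sets of equally scarce genes), which is consistent with a trace of liver transcripts. The splits behind this p move single libraries and break up the groups. They therefore cannot tell an effect shared by the modified groups from other differences between whole groups. Whether the liver transcripts come from carried-over RNA or may be made in testes given virus with the lncRNA constructs was not tested.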
